A study of Mus musculus with 22 samples.

How the data were processed

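Messenger RNA was sequenced from splenic natural killer (NK) cells of female and male mice, from the mouse pancreatic cancer line Panc02 in culture, and from Panc02 tumours grown as allografts in mice of both sexes. Per the labels' protocols, RNA integrity numbers lay between 8.5 and 10. Polyadenylated RNA was enriched from 100 ng (cell culture) or 500 ng (allografts) and strand-specific libraries were made. Fresh NK cells are described there as positively sorted, with RNA taken on oligo(dT) beads, whereas RNA from cell experiments and tumours was taken with phenol reagent, so fresh and cultured libraries also differ in how RNA was extracted.

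The deposited values are whole-number read counts per gene, not normalised. Per the submitters' processing notes, cutadapt 4.4, HISAT2 2.2.1, SAMtools 1.19.2 and featureCounts 2.0.6 were used with the mouse build GRCm39. Per the file headers, reads were assigned to exons of Ensembl release 113 genes with reverse-strand counting (setting 2). The headers also show that each mate of a pair was counted on its own and that multi-mapping reads were counted. Between 66.4% and 78.6% of the genes with 1 to 20 counts in a library had an even count, against 50% by chance, so most fragments count as a pair of reads and counting error is larger than the counts imply. Near-identical paralogs share multi-mapped reads, and values of such genes are uncertain. The tables hold 78298 genes, of which 51498 IDs were matched to a symbol through the reference gene table, and these held 97.1% to 99.1% of each library's counts. All 37 genes of the mitochondrial chromosome were at 0 in every library, so no share of mitochondrial reads could be given. The gene ENSMUSG00000119584 (chromosome 17, 40157244 to 40159092), which has no symbol in that table, took 0.09% to 1.98% of counts.

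Libraries were grouped by their labels into 9 groups: fresh, monocultured and co-cultured NK cells of each sex with 2 libraries per group, cultured Panc02 cells with 2, and allografts with 4 per host sex. The labels put the co-culture libraries under both Panc02 and primary NK cells and do not say whether the cell types were separated. They name donors as female or male and number the samples, without saying that each sample came from its own animal or that a number marks the same animal across conditions, so p-values measure the spread between these samples, part of which is possibly technical. No pair of libraries was alike within counting error: chi-square per gene between libraries of a group was 5.25 to 233. Total counts ranged from 13025549 to 46842646 per library, and 14676 to 21333 genes had at least 10 counts.

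Levels are CPM values, a gene's counts scaled to the total gene count of its library, given as mean ± SD over libraries. Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. A gene is said to rise, fall or change only where its adjusted p was below 0.05. Log2 fold changes are given with a standard error (SE) obtained as the fold change divided by the square root of F. All 12 NK and co-culture libraries entered a single fit of 6 group means (21414 genes, 6 residual degrees of freedom, biological coefficient of variation 0.127), because groups of 2 give little information on the spread by themselves. The co-cultures fitted with cultured Panc02 had a coefficient of variation of 0.0601. The pooled spread is thus not that of NK cells alone and may be too small for them. The 8 allografts were fitted alone for host sex (20560 genes, coefficient of variation 0.363) and with cultured Panc02 for growth in a host (23264 genes, 0.372). For sex across conditions, counts were also summed over the 3 libraries that share a sample number (22141 genes). Fold changes against groups with 0 counts in every library are given as lower bounds against a floor of 3 counts over the group. They cover the counting error of single reads only. Most fragments count as a pair of reads, so these bounds may be too high.

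The 50 gene lists, fixed before the data were examined, cover NK functions, signalling, metabolism, stress responses, sex-linked genes, presentation, tumour mediators and markers of other cell types. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. For each list the members past the gene test were counted over all genes tested and with p adjusted over the list alone. The comparisons, their alternatives and the rule for named genes were also set before the data were examined. In each direction the rule took the 8 called genes with the largest fold change, at least 5 CPM in the higher group and no overlap between groups. It added up to 4 members of a described list by smallest p with any member going against them, a fixed set of NK and tumour genes, 5 sex-linked genes, and every gene where 20 or fewer were called.

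Several steps were chosen after the data had been seen. NK-restricted genes (319 autosomal genes at 20 CPM or more in monoculture and at least 2000 times their level in cultured Panc02) and Panc02-restricted genes (51 genes at 50 CPM or more in cultured Panc02, at most 0.05 CPM in fresh NK cells and at most 1 part in 20 of the cultured Panc02 level in monoculture) were used to estimate the share of each cell type's RNA in a library. A library's NK share was the median level of the first set as a percent of its monoculture level, and its Panc02 share the median of the second as a percent of its level in cultured Panc02. On simulated mixtures with 1%, 2%, 3%, 5% and 20% NK RNA the estimates were 1.01%, 2.01%, 3.01%, 5% and 19.9%. These mixtures were built from the same female monoculture levels that the estimate divides by. They do not test whether NK genes keep their monoculture level in co-culture. The NK-restricted genes were then tested between co-culture and monoculture with TMM scaling over these genes alone (factors 0.875 to 1.1 on their own total), and again with their total and no TMM factor. Co-cultures were set against cultured Panc02 (18172 genes), and co-cultures with female and male NK cells were compared over genes in which NK RNA, at its estimated share and at fresh or monoculture levels, makes up under 10% of the value.

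Alternative settings were DESeq2's median-ratio scaling within edgeR, no filter on low counts, DESeq2 1.42.0, voom with sample quality weights (limma), each library left out, the sample number as a block, fits on the compared groups alone, and omission of genes far higher in Panc02. The test steps were tested on simulated counts for the real genes, with 200 changed genes per comparison (60 of 319 for the NK-restricted genes). Changes of 4-fold were recovered for 93% of changed genes in co-culture against monoculture, 95% in monoculture against fresh, 94% for sex in fresh cells, 87% for sex in monoculture, 83% for sex in co-culture, 86% for host sex and 81% in allografts against culture. For 2-fold changes the shares were 87%, 91%, 71%, 74%, 80%, 33% and 29%. For the interaction with sex they were 66% in co-culture and 54% in culture at 2-fold, and 82% in both at 4-fold. For the interaction of the NK-restricted genes with sex in co-culture they were 40% at 2-fold and 100% at 4-fold. False calls made up 6.25%, 3.63%, 6.78%, 6.4%, 3.55%, 5.56% and 9.09% of calls, in the order of the 4-fold shares. The changed genes were few and drawn from genes above a minimum expected count, whereas 74.9% of genes were called in co-culture against monoculture. Scaling under changes at most genes and recovery at low counts were thus not tested. Tables were processed and drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.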

Results

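Counts per gene were available for 22 RNA sequencing libraries in 9 groups. Natural killer (NK) cells, innate lymphocytes that kill tumour cells without earlier priming, were taken from spleens of female and male mice. They were sequenced fresh, after 24 h of culture with interleukin-2 (IL-2, the cytokine that sustains and activates them), or after 24 h with IL-2 in co-culture with Panc02, a mouse pancreatic cancer line. Each condition had 2 libraries per sex. Panc02 cells cultured alone had 2 libraries, and Panc02 allografts had 4 from female and 4 from male hosts. The series asks whether sex shapes NK cell immunity against pancreatic cancer. Total counts were 13025549 to 37201687 in fresh cells, 14624113 to 46170885 in monoculture, 34357879 to 46799030 in co-culture, 42123781 and 46842646 in cultured Panc02, and 26140269 to 42078638 in allografts.

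Genes of the sex chromosomes followed the labels in every NK library. Xist (X chromosome, 102503972 to 102537573, GRCm39), the RNA that silences the inactive X chromosome of female cells, stood at 967 ± 20.7 CPM (SD, n = 2) in fresh female cells. It was at 758 ± 4.34 in female monoculture and 34 ± 0.764 in co-culture with female NK cells. It was at or below 0.117 CPM in each library with male NK cells and at 0.128 and 0.095 in cultured Panc02. The Y-linked RNA helicase gene Ddx3y (Y chromosome, 1260771 to 1286629) was at 134 ± 21.5 CPM in fresh male cells and 114 ± 13.5 in male monoculture. It had 0 counts in all libraries with female NK cells and in cultured Panc02. Eif2s3y, Kdm5d and Uty, also on the Y chromosome, likewise had 0 counts in all of those.

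Co-culture libraries held mostly Panc02 RNA. Over 319 NK-restricted genes the median level was 2.80% and 3.40% of monoculture with female NK cells and 2.08% and 1.73% with male NK cells, while 51 Panc02-restricted genes stood at 92.5% to 95.0% of their level in cultured Panc02. The NK share averaged 3.10% ± 0.42 (SD, n = 2) with female and 1.90% ± 0.25 (n = 2) with male NK cells, a ratio of 1.63. The exact two-sided permutation p of 0.333 is the smallest that 2 against 2 libraries can give. Of sex-linked transcripts of NK cells, Xist in co-culture with female NK cells was at 4.41% and 4.55% of monoculture, above the estimate from the NK-restricted genes. Ddx3y with male NK cells was at 2.01% and 1.89%, so that these genes put the ratio at 2.3. That ratio sets a gene of female cells against a different gene of male cells. It holds as a ratio of NK shares only if neither gene changes within NK cells in co-culture. Monoculture libraries in turn held a trace of Panc02 transcripts, at 0%, 0.314%, 0.142% and 0.323% of cultured Panc02 in female 1, female 2, male 4 and male 5. The labels do not say whether the cell types were separated, so differences against co-culture compare mixtures of cells.

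**Figure D1:**
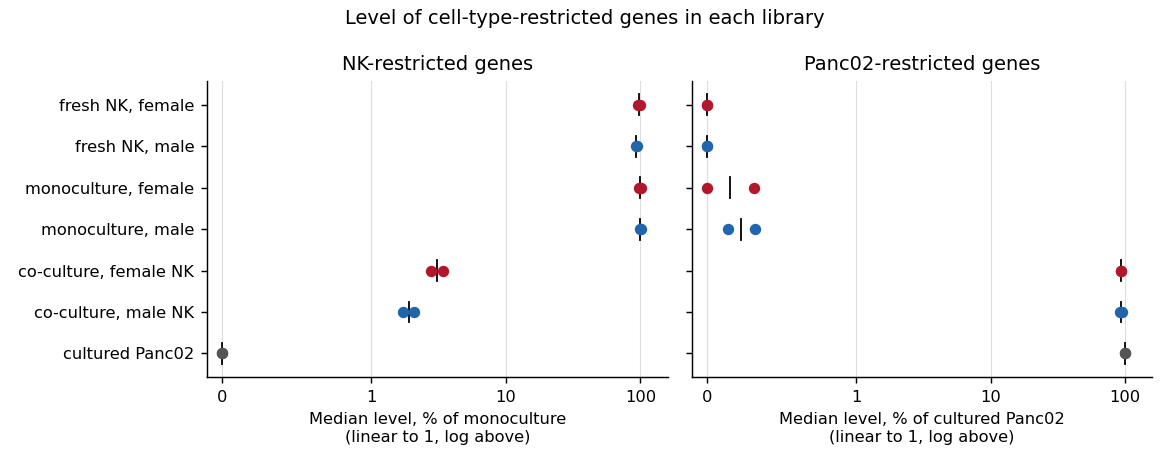
Estimated RNA shares per library (points) with group means (bars): median level of NK-restricted genes in percent of monoculture and of Panc02-restricted genes in percent of cultured Panc02, on an axis that is linear up to 1% and logarithmic above. Co-culture libraries sit at 1.73% to 3.40% for NK genes and at 92.5% to 95.0% for Panc02 genes.

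After 24 h of culture with IL-2, NK cell libraries had stress-response and IL-2 target genes higher and cell cycle genes lower than libraries of fresh cells. Trib3 (chromosome 2, 152179342 to 152185952), a pseudokinase induced by the transcription factor ATF4 when amino acids run short, stood at 0.443 ± 0.409 CPM in female and 0.677 ± 0.411 in male fresh cells and at 162 ± 9.4 and 148 ± 6.9 in monoculture (SD, n = 2 each). Its log2 fold change was 8.01 ± 0.17 (SE, edgeR with Benjamini-Hochberg adjustment, adjusted p = 9.24e-14). Chac1, a glutathione-degrading enzyme of the same response, rose by 10.70 ± 0.32 on the log2 scale and Aldh1l2, a mitochondrial folate enzyme, by 9.19 ± 0.50. Ppp2r2c, a regulatory subunit of protein phosphatase 2A, had 0 counts in all fresh libraries and stood at 61.6 ± 9.43 and 48 ± 3.53 CPM in monoculture, at least 1930-fold higher. Bcat1, which starts the breakdown of branched amino acids, was at least 183-fold higher. Of 17 genes of the unfolded protein and integrated stress response, 14 rose and 0 fell, or 14 and 1 when adjusted over the list alone, among them Psat1 (2.08 ± 0.06) and Atf4 itself (1.75 ± 0.06). The camera test of that list gave an adjusted p of 1.17e-29, and 0.00906 with an estimated correlation.

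Cytotoxic genes moved in both directions in monoculture. Gzmb (chromosome 14, 56496295 to 56499717), the granule protease granzyme B, rose from 393 ± 81.8 and 636 ± 37.3 CPM in female and male fresh cells to 1350 ± 110 and 1540 ± 210 (1.63 ± 0.09, adjusted p = 1.88e-08). The pore-forming protein gene Prf1 (chromosome 10, 61133612 to 61140459) fell from 1200 ± 7.49 and 1360 ± 112 to 500 ± 39.3 and 598 ± 30.5 (-1.12 ± 0.09, adjusted p = 6.7e-07). The interferon gamma gene Ifng (chromosome 10, 118276951 to 118281797) rose by 1.22 ± 0.11 and Tnf by 2.41 ± 0.20. The death ligands Tnfsf10 and Fasl rose by 2.56 ± 0.11 and 0.95 ± 0.09 and the granzyme gene Gzma by 0.50 ± 0.10. The activating receptor gene Ncr1, which encodes NKp46, fell by 0.65 ± 0.05, while Klrk1, which encodes NKG2D, did not pass the test (0.06 ± 0.08, adjusted p = 0.585). Of 19 cytotoxic effectors 9 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.336). Among inhibitory receptors Tigit rose by 1.46 ± 0.11, and Havcr2, which encodes TIM-3, and Lag3 fell (-2.43 ± 0.28 and -1.08 ± 0.28). The call of Lag3 ended without fresh female 1 (adjusted p = 0.058). Pdcd1, which encodes PD-1, had group means at or below 0.316 CPM (adjusted p = 0.153). The IL-2 receptor alpha chain gene Il2ra rose by 1.45 ± 0.25.

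Of 22 targets of IL-2 and STAT5, 16 rose and 0 fell, also when adjusted over the list alone (camera 9.96e-16, and adjusted p = 0.0369 with an estimated correlation). Among them were the survival gene Bcl2 (2.58 ± 0.06) and the feedback inhibitors Cish (2.83 ± 0.08) and Socs1 (2.82 ± 0.08). Of 15 targets of p53 10 rose and 2 fell, again with equal counts when adjusted over the list alone (camera 7.01e-11, and adjusted p = 0.0421 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 9.41 ± 0.697 and 9.18 ± 0.393 to 180 ± 18.5 and 169 ± 8.76 CPM, and the pro-apoptotic gene Pmaip1 fell by 0.99 ± 0.17. All 31 cell cycle genes fell, also when adjusted over the list alone, among them Tk1 (-2.30 ± 0.08), Plk1 (-2.28 ± 0.09) and Cdk1 (-2.02 ± 0.09). The camera adjusted p was 3.16e-31, and 0.121 with an estimated correlation. Transcripts of red cell precursors and other cell types also fell in culture. Whether loss of such cells lowered the cell cycle genes was not tested. Of 21 genes of NK maturation and homing 6 rose and 13 fell, the same when adjusted over the list alone (camera 2.4e-06, and adjusted p = 0.0467 with an estimated correlation). Cx3cr1, a chemokine receptor of mature NK cells, fell by 4.51 ± 0.14 and Klrg1 by 2.92 ± 0.09, while the integrin gene Itga1 rose by 4.21 ± 0.18. Of 26 type I interferon genes 2 rose and 23 fell, also when adjusted over the list alone (camera 1.1e-06, but adjusted p = 0.104 with an estimated correlation). The nucleotide kinase gene Cmpk2 fell by 3.45 ± 0.18.

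Transcripts of other cell types were lower after culture. Klf1, the master regulator of red cell precursors, fell from 65 ± 13.7 and 84 ± 11.6 CPM to 0.0342 ± 0.0484 and 0.143 ± 0.103 (-10.18 ± 0.35, adjusted p = 2.08e-10). The erythroid gene Rhag fell by 10.79 ± 0.36. Cldn13, a claudin, and Cd248, a stromal surface protein, reached 0 counts in monoculture, at least 540-fold and 245-fold lower. All 9 dendritic cell genes fell, also when adjusted over the list alone (camera 1.11e-09, and adjusted p = 0.0113 with an estimated correlation), among them Fscn1 (-4.33 ± 0.13) and Flt3 (-4.03 ± 0.28). All 6 platelet genes fell, such as Gp5 (-4.09 ± 0.30), again also when adjusted over the list alone (camera 0.00141, but adjusted p = 0.244 with an estimated correlation). Of 12 endothelial genes 9 fell and 1 rose, or 10 and 1 when adjusted over the list alone (camera 2.28e-05, but adjusted p = 0.173 with an estimated correlation). Of 8 epithelial genes 6 rose, also when adjusted over the list alone (camera 0.0438, but adjusted p = 0.269 with an estimated correlation), such as Krt8 (7.96 ± 1.67) and Cdh1 (3.16 ± 0.29). The call of Krt8 ended without monoculture female 2 (adjusted p = 0.095), a library with a Panc02 trace of 0.314%.

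In all, 4742 of 21414 genes rose and 4513 fell between fresh cells and monoculture by edgeR. Which direction had more genes depends on the processing, with 4043 and 5035 by median-ratio scaling, 3993 and 4898 by DESeq2, 4120 and 4594 without the filter, and 3349 and 4764 without monoculture female 2. Of the 36 lists tested, camera called 20, and 5 of these calls held with an estimated correlation. For 118 of the 4742 genes the rise was no more than 2 times what the largest trace of Panc02 RNA, 0.323%, would bring, and fresh and cultured cells also differ in how RNA was extracted.

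**Figure D2:**
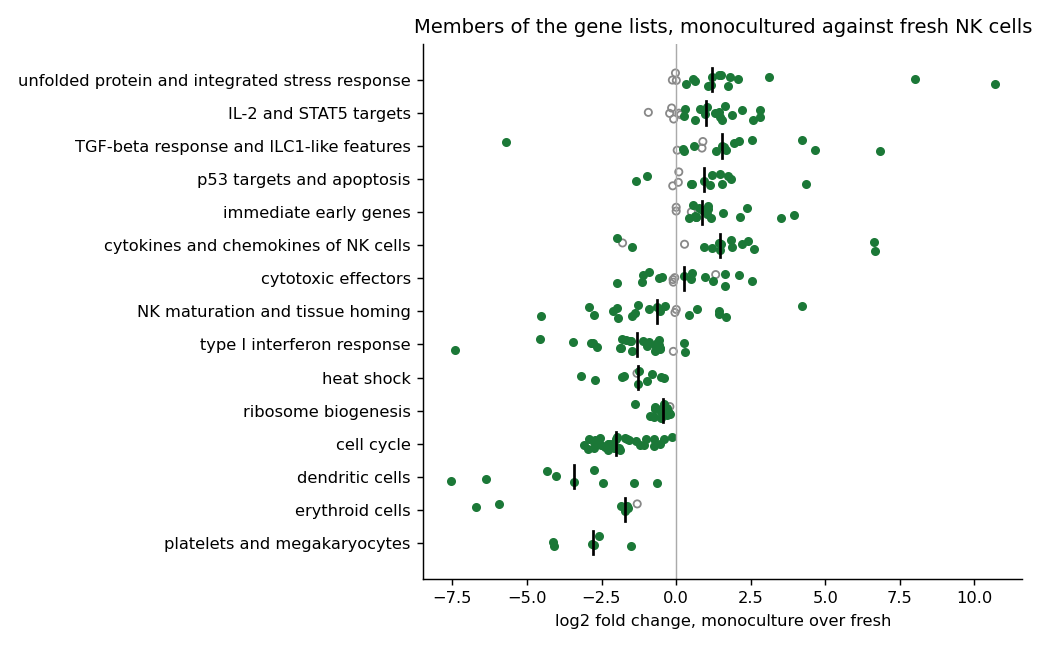
Log2 fold change of each measured member (points) of 15 gene lists in monocultured against fresh NK cells, filled where the adjusted p was below 0.05, with the list median as a line. All 31 cell cycle genes lie below 0, and 14 of 17 stress-response genes are filled and above 0.

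Fresh NK cells differed between the sexes at many genes of modest change. Gzmb was lower in female than in male cells, at 393 ± 81.8 against 636 ± 37.3 CPM (SD, n = 2 each). Its log2 fold change was -0.72 ± 0.13 (SE, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00509). The inhibitory receptor gene Tigit (chromosome 16, 43469230 to 43484509) was also lower, at 24.4 ± 0.688 against 67.8 ± 18.8 (-1.49 ± 0.16, adjusted p = 0.000473). Serpinb6b and Serpinb9, inhibitors that protect killer cells from granule proteases, were lower in female cells (-0.78 ± 0.08 and -0.75 ± 0.11), and the granule protease gene Ctsw was higher (0.50 ± 0.10). Prf1 (-0.20, adjusted p = 0.385), Gzma (0.27, adjusted p = 0.295), Ifng (0.04, adjusted p = 0.938), Fasl (-0.40, adjusted p = 0.06) and Ncr1 (0.21, adjusted p = 0.0698) passed no threshold. Of 19 cytotoxic effectors 2 were higher and 7 lower in female cells, or 2 and 8 when adjusted over the list alone (camera 0.00144, but adjusted p = 0.642 with an estimated correlation). The call of Ctsw ended without fresh female 1 or fresh male 5 (adjusted p = 0.0739 and 0.0588). Eomes, a transcription factor of NK cell development, was higher in female cells (551 ± 11.6 against 398 ± 18 CPM, adjusted p = 0.00325). Of 19 immediate early genes 2 were higher and 3 lower, the latter with Nr4a1 (-1.28 ± 0.14) and Egr3 (-0.92), and the counts were equal when adjusted over the list alone (camera 0.0673). Of 22 targets of IL-2 and STAT5 2 were higher and 4 lower, or 3 and 7 when adjusted over the list alone (camera 0.668), with Socs1 at -0.99 ± 0.11.

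Of 31 cell cycle genes 13 were lower in female fresh cells and 0 higher, or 16 and 0 when adjusted over the list alone (camera 1.69e-10, but adjusted p = 0.707 with an estimated correlation). Bub1b, of the spindle checkpoint, was at 37.5 ± 3.74 against 60.1 ± 1.41 CPM (-0.71 ± 0.09), and Cdk1 at 29.7 ± 2.9 against 44.8 ± 0.688 (-0.62 ± 0.11). Among the largest changes, the dendritic cell transcription factor Batf3, the amino acid oxidase Il4i1 and the chemokine Cxcl16 were higher in female cells by 1.52 ± 0.44, 1.45 ± 0.24 and 1.26 ± 0.25. Without fresh female 1 the calls of all 3 ended (adjusted p = 0.306, 0.0551 and 0.121), that of Batf3 also without fresh male 5 or 4 (0.24 and 0.128) and that of Cxcl16 without fresh male 4 (0.0529). The neutrophil granule genes Mpo and Prtn3 were lower in female cells, Mpo at 5.38 ± 0.114 against 50.5 ± 41.2 CPM (-3.25 ± 0.66, adjusted p = 0.0375) and Prtn3 by -2.90. Mpo lost its call in 10 fits without a library (adjusted p from 0.0567 to 0.313, highest without fresh female 1) and Prtn3 in 5 (0.059 to 0.368, highest without fresh male 5, with -1.56). Of 13 neutrophil genes 1 was lower, or 5 when adjusted over the list alone (camera 0.00132, but adjusted p = 0.791 with an estimated correlation). Of 7 plasma cell genes 2 were lower, or 6 when adjusted over the list alone (camera 0.00137, but adjusted p = 0.144 with an estimated correlation). Of 7 X-linked genes that escape inactivation, Xist among them, 3 were higher and 0 lower, also when adjusted over the list alone (camera 7.77e-42, and adjusted p = 0.000936 with an estimated correlation). The histone demethylase genes Kdm5c and Kdm6a were higher by 0.55 ± 0.08 and 0.42, the latter with adjusted p = 0.0718 without fresh male 5 and 0.0526 without fresh female 2.

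In all, 947 genes were higher and 1202 lower in female fresh cells by edgeR, of which 912 and 1155 were autosomal, and 5 of 36 lists were called. Single libraries moved these counts: 569 genes were called without fresh female 1, 1031 without fresh male 4, 916 without fresh male 5 and 3421 without monoculture female 2. The balance also moved, with 662 higher and 2759 lower in the last of these and 562 and 2521 without the filter. With the 4 fresh libraries fitted alone 1340 were called, 645 higher and 695 lower.

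In monoculture edgeR called 23 genes between the sexes, of which 5 were X-linked, 5 Y-linked and 13 autosomal. Besides Xist (758 ± 4.34 against 0.102 ± 0.0216 CPM), the escape genes Kdm6a (0.76 ± 0.09, adjusted p = 0.000802), Kdm5c (0.59, adjusted p = 0.00183) and Eif2s3x (0.41, adjusted p = 0.0244) and the X-linked long non-coding RNA Firre (1.35 ± 0.19, adjusted p = 0.00389) were higher in female cells. Ddx3y, Eif2s3y, Kdm5d and Uty were at least 1940-fold, 1750-fold, 906-fold and 392-fold lower. The calls of Kdm5c without monoculture female 2 (adjusted p = 0.0806) and of Firre without monoculture male 5 (0.0533) ended, and that of Eif2s3x ended in 6 fits without a library (0.0502 to 0.165, highest without monoculture female 2). Autosomal genes numbered 7 higher and 6 lower. Rab6b, a vesicle traffic gene, was higher (83.8 ± 11.8 against 45.2 ± 1.78 CPM, 0.87 ± 0.10, adjusted p = 0.000802). Slc25a4, the mitochondrial carrier of ADP and ATP, was lower (28.2 against 45 CPM, -0.72 ± 0.09, adjusted p = 0.000937). Gzmb (-0.22, adjusted p = 0.793), Prf1 (-0.29, adjusted p = 0.718), Ifng (-0.30, adjusted p = 0.764) and Tigit (-0.06, adjusted p = 0.986) passed no threshold. Of 7 escape genes 4 were higher, also when adjusted over the list alone (camera 6.4e-134, and adjusted p = 3.4e-05 with an estimated correlation). Of 13 neutrophil, 16 cytokine and chemokine, 22 oxidative phosphorylation, 13 macrophage, 7 plasma cell and 18 cholesterol synthesis genes 0 were called, or 1, 4, 1, 1, 2 and 2 lower in female cells when adjusted over the list alone. Camera called these 6 lists lower (2.44e-05, 0.00274, 0.00587, 0.00804, 0.00811 and 0.00972, but adjusted p = 0.769, 0.341, 0.894, 0.239, 0.239 and 0.833 with an estimated correlation). All told, edgeR called 12 genes higher and 11 lower, where 1468 had an unadjusted p under 0.05. DESeq2 called 75 genes, the unfiltered fit 207 and the 4 libraries fitted alone 12, and 71, 53 or 43 were called without monoculture female 1, female 2 or male 4, of which 45, 38 and 33 were lower.

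The effect of culture itself differed between the sexes at 546 genes, 215 with a higher and 331 with a lower fold change in female cells. Tigit rose more in female cells (difference of log2 fold changes 1.43 ± 0.21, adjusted p = 0.00819), as did the interleukin-33 receptor gene Il1rl1 (2.15 ± 0.34). Cx3cr1 fell further in female cells (-1.41 ± 0.26), from 81.2 to 2.13 CPM against 60.3 to 3.99, as did Apoe, a lipid carrier of macrophages (-1.23 ± 0.19). The call of Tigit ended without fresh female 1 (adjusted p = 0.0794) and that of Cx3cr1 without monoculture female 2 (0.0779). Gzmb did not pass (0.50, adjusted p = 0.173). Of 31 cell cycle genes 2 had a higher fold change, or 8 when adjusted over the list alone (camera 2.82e-05, but adjusted p = 0.933 with an estimated correlation). Of 20 activating receptor genes 0 were called, or 2 with a lower fold change when adjusted over the list alone (camera 0.0387, but adjusted p = 0.933 with an estimated correlation). With median-ratio scaling the split was 417 higher and 265 lower, and with DESeq2 901 and 551. The count of 546 became 186 without fresh female 1, 935 without fresh female 2, 347 without fresh male 4, and 180 without fresh male 5. It became 274 without monoculture male 5, 355 without co-culture male 4 and 352 without co-culture male 5.

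With counts summed over the 3 conditions of each sample number, 9 genes were higher and 24 lower in the sums of female samples. Libraries of co-culture made up 47.2% and 48.8% of the female and 32.3% and 36.4% of the male sums, so the sums also differ in their part of Panc02 RNA, and these counts do not measure NK cells alone. Xist was higher, Ddx3y at least 5120-fold and Uty at least 1030-fold lower, and the actin regulator Mical2 was higher by 0.51 ± 0.06 (adjusted p = 0.0477, and 0.448 or 0.157 without sample 4 or 5). Of 14 NK identity genes 0 were called, or 10 lower when adjusted over the list alone (camera 9.47e-10, but adjusted p = 0.588 with an estimated correlation), the direction that a larger part of co-culture libraries gives. Camera called 15 of 36 lists, 4 higher and 11 lower, and 0 held with an estimated correlation. Here edgeR had 4018 genes at an unadjusted p under 0.05, DESeq2 called 1332 (779 higher and 553 lower), the unfiltered fit 2082 and voom 6, and without sample 1, 2, 4 or 5 edgeR called 1625, 3092, 9 or 5.

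Set against monoculture, libraries labelled co-culture had genes abundant in cultured Panc02 higher and NK genes lower. Ccbe1, a regulator of lymph vessel growth, had 0 counts in monoculture and stood at 23.5 ± 4.02 and 27.1 ± 3.03 CPM in co-culture with female and male NK cells (SD, n = 2 each), at least 1180-fold higher. In cultured Panc02 it stood at 30 CPM. The transcription factor gene Foxq1 was at least 1120-fold higher, and Onecut2 and the growth factor gene Pdgfc rose by 12.42 and 11.92 on the log2 scale. All 31 cell cycle and all 18 cholesterol synthesis genes rose, also when adjusted over the list alone (camera 2.89e-16 and 7.6e-10, but adjusted p = 0.257 and 0.0889 with an estimated correlation). All 14 NK identity genes and all 20 activating receptor genes fell, also when adjusted over the list alone (camera 4.39e-32 and 2.73e-25, and adjusted p = 0.00757 and 0.00426 with an estimated correlation). Gzmb fell from 1350 ± 110 to 110 ± 4.69 CPM with female and from 1540 ± 210 to 59.7 ± 5.69 with male NK cells (-4.05 ± 0.10). Prf1 fell from 500 ± 39.3 to 42.7 ± 9.65 and from 598 ± 30.5 to 24 ± 0.197 (-3.99). Likewise Ifng fell by 4.16, Ncr1 by 5.16, Klrk1 by 5.33 and Gzma by 5.40. Tigit, at 203 ± 14 CPM in cultured Panc02 itself, rose from 104 ± 6.35 and 106 ± 7.09 to 208 and 213, and Havcr2, at 10.4 in Panc02, rose by 4.04.

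In all, edgeR called 7784 genes higher and 8260 lower in co-culture, 7141 and 6983 with female cells, and 6933 and 7361 with male cells. Of the 7784, 84.6% would need no more Panc02 RNA than the libraries are estimated to hold, and 8236 of the 8260 were higher in monoculture than in cultured Panc02. Between the sexes the fold change differed at 217 genes, 204 of them higher with female cells. Gzmb was higher by 1.07 ± 0.18 (adjusted p = 0.0141), Prf1 by 1.10 ± 0.19 (adjusted p = 0.0154) and Ifng by 1.23 ± 0.26 (adjusted p = 0.0279). The receptor genes Klrk1 and Ncr1 were higher by 0.84 ± 0.16 (adjusted p = 0.0214) and 0.75 ± 0.11 (adjusted p = 0.00316), where Gzma (0.89, adjusted p = 0.112) and Fasl (0.89, adjusted p = 0.0555) passed no threshold. Without co-culture male 5 the calls of Gzmb, Prf1, Ifng and Klrk1 ended (adjusted p = 0.0985, 0.116, 0.201 and 0.0955). Those of Gzmb and Ifng also ended without co-culture female 2 (0.0949 and 0.0895), and in 4 to 6 fits without a library those of Ifng, Klrk1 and Prf1. Of 14 NK identity genes 8 had a higher fold change with female cells, or 13 when adjusted over the list alone (camera 7.58e-29, and adjusted p = 0.0121 with an estimated correlation), while the estimated NK share was 1.63 times as high there. Camera called 15 of 36 lists, 14 higher and 1 lower, and 11 held with an estimated correlation. Without co-culture female 2 or male 5 the count of 217 became 126 or 92, and it was 337 with DESeq2, 83 with voom and 529 without the filter.

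Relative to the other NK-restricted genes, Prf1, Gzmb and Ifng stood higher in co-culture than in monoculture, and Tnfsf10 lower. The 319 genes were picked by their level in monoculture against cultured Panc02, and 10 of them are on lists of markers of other cell types. With TMM scaling over the 319 genes, Prf1 rose by 1.28 ± 0.07 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 4.4e-10). Scaled to the total of these genes alone, without TMM, log2 fold changes were lower by a median of 0.238, with Prf1 at 1.04 ± 0.07, Gzmb at 0.98 ± 0.07 and Ifng at 0.88 ± 0.14. On that scale Prf1 went from 6870 to 15600 CPM of those genes with female and from 7920 to 14800 with male NK cells. The values that follow are with TMM. Gzmb rose by 1.22 ± 0.07 (adjusted p = 3.78e-08) and Ifng by 1.12 ± 0.14 (adjusted p = 5.78e-06). The chemokines Ccl4, Xcl1 and Ccl3 rose by 1.87 ± 0.09, 1.85 ± 0.11 and 0.82 ± 0.09, the death ligand Fasl by 0.53 ± 0.09 and the IL-2 receptor chain Il2rb by 0.74 ± 0.05. Lower were the receptor gene Klrb1 (-3.25 ± 0.39, adjusted p = 3.3e-06), the muscle-type respiratory subunit Cox6a2 (-4.58 ± 0.66) and the integrin gene Itga1 (-1.16 ± 0.20). Co-culture libraries held 60094 to 137081 counts of the 319 genes, so Klrb1 and Cox6a2 rest on few counts there. With female and male NK cells Klrb1 was at 80.5 ± 51.2 and 21.7 ± 30.7 CPM of those genes, and Cox6a2 at 14.6 ± 20.6 and 83.2 ± 118. The transcription factor Tox (-1.26 ± 0.25), the signalling adaptor Fcer1g (-0.73 ± 0.07) and the death ligand Tnfsf10 (-0.70 ± 0.15) were also lower. Gzma was at -0.13 ± 0.05 (adjusted p = 0.0497), above 0.05 in 6 of 8 fits without a library (0.0517 to 0.243, highest without co-culture female 1), while Ncr1 (0.13, adjusted p = 0.271) and Klrk1 (-0.06, adjusted p = 0.415) passed no threshold. By the total alone Ncr1 was at -0.11 (adjusted p = 0.23), the opposite direction, and Gzma (-0.37, adjusted p = 0.000183) and Klrk1 (-0.30, adjusted p = 0.000684) fell. Of 6 cytokine and chemokine genes 4 rose and 0 fell, or 4 and 1 when adjusted over the list alone (camera 0.000526, but adjusted p = 0.244 with an estimated correlation). Of 8 cytotoxic effectors 3 rose and 3 fell, also when adjusted over the list alone (camera 0.117).

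Of 6 genes of the interferon gamma response 5 rose, or 6 when adjusted over the list alone (camera 0.00389, but adjusted p = 0.244 with an estimated correlation). The interferon-inducible GTPases Tgtp2 and Gbp4 rose by 5.26 ± 0.23 and 1.82 ± 0.14. Such genes could also be made by Panc02 cells in co-culture, and Tgtp2 shares reads with its near-identical copy Tgtp1. Of the 14 activating receptor genes 1 rose and 6 fell, and of the 6 inhibitory receptor genes 0 rose and 4 fell, with the same counts when adjusted over the list alone (camera 0.117 for both). In all, 77 of the 319 genes rose and 70 fell, or 59 and 122 by the total alone, so the balance between rises and falls depends on the scaling. Of these calls 129 were shared and 0 went in opposite directions. Between the sexes edgeR called 0 of the 319 fold changes different, as it did by the total alone and in each of the 8 fits that left out a library. Gzmb was at 0.37 (adjusted p = 0.578), Prf1 at 0.37 (adjusted p = 0.471) and Ifng at 0.54 (adjusted p = 0.763). On simulated counts this test recovered 40% of genes changed by 2-fold, so differences of this size could be missed. At an unadjusted p under 0.05 edgeR had 21 genes, while DESeq2 and voom called 0 each. Of 6 cytokine and chemokine genes 0 were called, or 2 higher with female cells when adjusted over the list alone (camera 0.0242, but adjusted p = 0.577 with an estimated correlation), and the other 6 lists were not called.

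**Figure D3:**
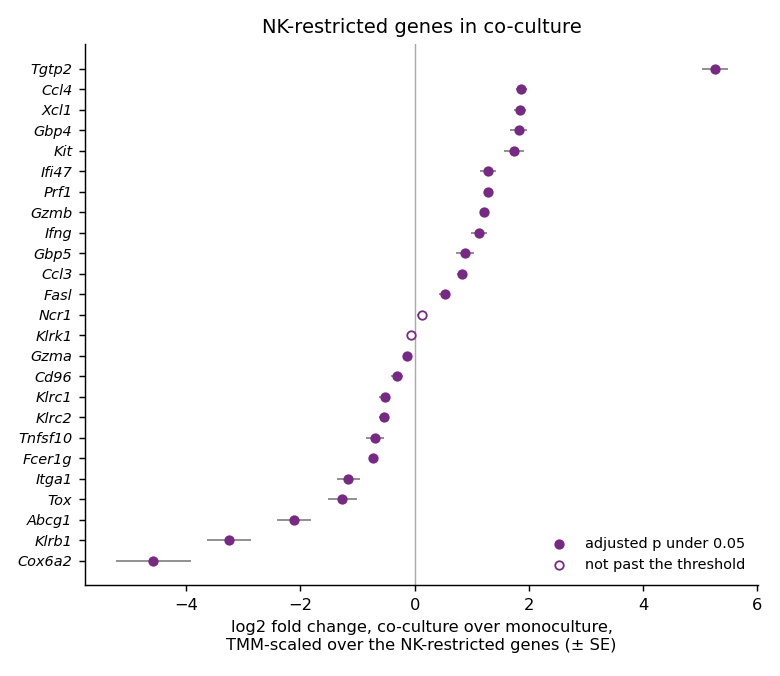
Log2 fold change ± SE of 25 NK-restricted genes in co-culture against monoculture, with TMM scaling over the 319 NK-restricted genes, filled where the adjusted p was below 0.05. Prf1, Gzmb and Ifng lie at 1.28, 1.22 and 1.12, and Klrb1, with few counts in co-culture, at -3.25. Scaled to the total of these genes alone, values were lower by a median of 0.238, with Ncr1 at -0.11.

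Interferon response genes were higher in co-culture than in Panc02 cells alone, and higher with female than with male NK cells. Irf1 (chromosome 11, 53660841 to 53669200), a transcription factor induced by interferon gamma, stood at 22 ± 0.908 CPM in cultured Panc02, 173 ± 16.7 with female and 98.8 ± 4.61 with male NK cells (SD, n = 2 each). The class I antigen presentation gene H2-K1 stood at 32.9 ± 1.15, 191 ± 4.7 and 116 ± 6.43. The checkpoint ligand gene Cd274, which encodes PD-L1 (chromosome 19, 29344855 to 29365495), stood at 1.37 ± 0.341, 20.1 ± 4.18 and 9.31 ± 0.153. The interferon-inducible GTPase gene Irgm2 (chromosome 11, 58090444 to 58113608) stood at 0.0356, 61.9 ± 12.7 and 25.8 ± 3.49.

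Against Panc02 cells alone, Irf1 rose by 2.62 ± 0.06 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 4.99e-17) and H2-K1 by 2.23 ± 0.05 (adjusted p = 4.99e-17). Cd274 rose by 3.38 ± 0.18 (adjusted p = 6.58e-12). Iigp1, another interferon-inducible GTPase, was at least 1360-fold higher. All 23 interferon gamma response genes and all 13 class I presentation genes rose, also when adjusted over the list alone (camera 5.28e-103 and 2.72e-82, and adjusted p = 0.0189 with an estimated correlation for both). Of 19 immediate early genes 17 rose, or 18 when adjusted over the list alone (camera 5.6e-20, and adjusted p = 0.0228 with an estimated correlation), such as Egr1 (0.77 ± 0.05). Of 16 ligands of NK receptors 8 rose and 0 fell, or 8 and 1 when adjusted over the list alone (camera 4.62e-15, and adjusted p = 0.0228 with an estimated correlation). Co-culture libraries also held NK RNA, which can add to these rises. Among genes with little NK RNA, compared below, were 8 of the 23 interferon gamma and fewer than 5 of the 13 class I genes. They also held 12 of the 19 immediate early genes and 7 of the 16 ligands. How much of the rise of the other members came from NK RNA was not tested. Of 31 cell cycle genes 3 rose and 1 fell, or 1 and 1 when adjusted over the list alone (camera 0.861). The long non-coding RNA Malat1 fell from 486 to 264 and 192 CPM (-1.06 ± 0.10, adjusted p = 0.0028, and 0.0689 or 0.0567 without co-culture female 2 or 1). In all, 2212 genes rose and 1113 fell, part of them NK transcripts such as Gzma and Prf1, at least 2510-fold and 1010-fold higher. Gzma had an adjusted p of 0.0656 or 0.0573 without co-culture male 5 or 4, and the count of 3325 became 1527 or 1934 without cultured Panc02 1 or 2. The labels do not say whether the cultured Panc02 cells were given IL-2.

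**Figure D4:**
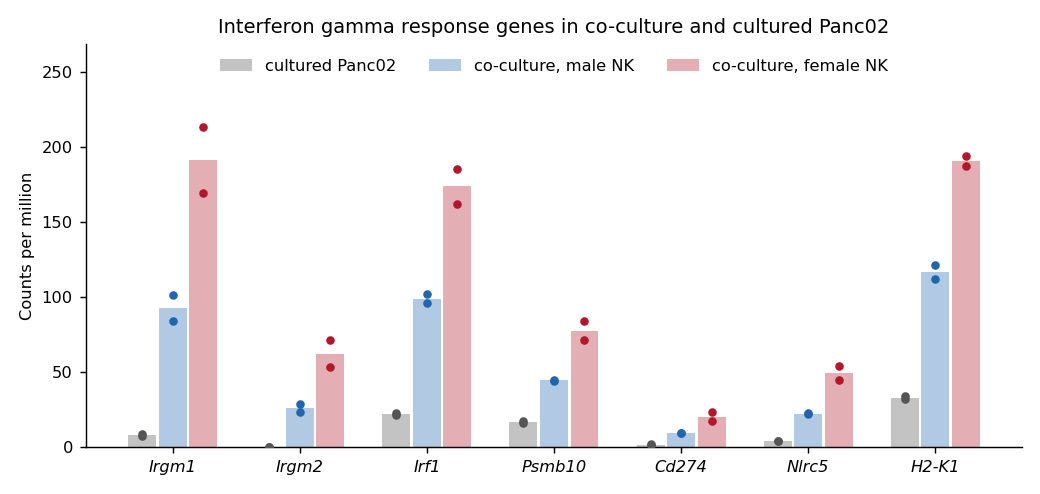
Levels in CPM of 7 interferon response genes in cultured Panc02 and in co-culture with female and male NK cells, with bars for the mean and points for the 2 libraries of a group. Irf1 stands at 22, 173 and 98.8 CPM and Cd274 at 1.37, 20.1 and 9.31 in the 3 groups.

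Between co-cultures, edgeR called 275 genes higher and 5 lower with female than with male NK cells in the fit of 12 libraries. Irgm2 was higher by 1.24 ± 0.13 (adjusted p = 7.39e-05) and its relative Tgtp1 by 1.31 ± 0.14 (adjusted p = 0.000104), though the latter shares reads with a copy. NK transcripts such as the receptor gene Cd96 (1.35) and the granzyme gene Gzmc (1.84 ± 0.42, adjusted p = 0.0372) were also higher. The call of Gzmc ended without co-culture male 4, female 2 or female 1 (adjusted p = 0.444, 0.275 and 0.097). Of 23 interferon gamma response genes 16 were higher and 0 lower, or 19 and 0 when adjusted over the list alone, with a camera adjusted p of 4.85e-75 and 0.000611 with an estimated correlation. Of 13 class I presentation genes 12 were higher, also when adjusted over the list alone (camera 1.02e-57, and adjusted p = 0.000149 with an estimated correlation). H2-K1 and Tapbp were higher by 0.69 and 0.63, and Psmb10 and Nlrc5 by 0.78 and 1.13. The log2 ratio of mean NK shares was 0.702. Fewer than 5 of the 13 had under 10% NK RNA, so for this list more NK RNA cannot be told apart from other explanations. Of 14 NK identity genes 9 were higher, or 13 when adjusted over the list alone (camera 3.09e-37, and adjusted p = 0.0073 with an estimated correlation), beside the NK share that was 1.63 times as high. Camera called 18 of 36 lists, 15 higher and 3 lower (neutrophils, glycolysis and hypoxia, and cholesterol synthesis), and 11 held with an estimated correlation. The count of 280 was 176 without co-culture female 2, 131 without male 5, 122 with voom, 444 without the filter and 176 with the 4 libraries fitted alone.

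Over genes in which NK RNA at fresh or monoculture levels makes up under 10% of the value, 31 were higher and 4 lower with female NK cells. The largest called change was that of Gzmc (1.83 ± 0.30, adjusted p = 0.00738, or 0.0823 without co-culture male 4), an NK gene with 0 counts in cultured Panc02, which stood at 2.82 and 2.17 CPM in female and male monoculture and at 6.66 ± 0.558 and 1.8 ± 1.02 in co-culture. Genes that NK cells make more of in co-culture are thus not kept out. Irf1 was higher by 0.78 ± 0.06 (adjusted p = 5.17e-07) and the immunoproteasome subunit Psmb10 by 0.78 ± 0.07 (adjusted p = 6.62e-06). Cd274 was higher by 1.08 ± 0.15 (adjusted p = 0.000799), the chemokine Cxcl10 by 1.42 ± 0.25 (adjusted p = 0.0122) and Irgm2 by 1.24 ± 0.15 (adjusted p = 0.0192). The call of Cxcl10 ended without co-culture female 1, male 4 or male 5 (0.458, 0.121 and 0.106). The secreted glycoprotein gene Spp1 was lower (-0.23 ± 0.03, adjusted p = 0.00101). Irgm1 did not pass here (1.02, adjusted p = 0.223), though it did at the same fold in the edgeR fit of 12 libraries (adjusted p = 2.61e-05). Raet1e, a ligand of NKG2D, did not pass either (-0.08, adjusted p = 0.737). Of 8 interferon gamma response genes 3 were higher, or 8 when adjusted over the list alone (median 1.17, camera 1.57e-39, but adjusted p = 0.254 with an estimated correlation). Camera called 14 of 24 lists, 6 higher and 8 lower, and 0 held with an estimated correlation, nor did fry call any. Among those lower with female NK cells, of 20 glycolysis and hypoxia genes 0 were called, or 4 lower when adjusted over the list alone (median -0.19, camera 8.82e-07, but adjusted p = 0.479 with an estimated correlation). Of 31 cell cycle genes 0 were called, also when adjusted over the list alone (median -0.04, camera 0.000727, but adjusted p = 0.31 with an estimated correlation). The count of 35 was 119 without co-culture female 2, 53 with DESeq2 and 157 without the filter.

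Allografts of female and male hosts differed in Y-linked genes alone by edgeR. Uty had 0 counts in female hosts and stood at 3.26 ± 0.683 CPM in male hosts (SD, n = 4 each), at least 154-fold lower in female hosts. Kdm5d and Eif2s3y were lower by -8.29 ± 0.71 and -7.64 ± 0.72 on the log2 scale, and each of the 3 genes had an adjusted p of 0.0115 (edgeR with Benjamini-Hochberg adjustment). Xist (98 ± 49.6 against 2.82 ± 4.09 CPM) and Ddx3y (0.138 ± 0.275 against 12.1 ± 2.41) lay in the direction of the hosts' sex but passed no threshold (adjusted p = 0.19 for both). Of NK and immune genes, Ncr1 was at 1.3 ± 0.957 against 0.576 ± 0.213 CPM (1.24 ± 0.67, adjusted p = 0.404). Gzmb was at 5.15 ± 2.14 against 4.76 ± 1.99 and Ifng at 1.35 ± 1.28 against 0.935 ± 0.276. The chemokine Cxcl9 was at 329 ± 323 against 261 ± 52.9, the T cell gene Cd8a at 20.7 ± 12.9 against 15.8 ± 3 and the regulatory T cell factor Foxp3 at 7.4 ± 2.53 against 7.5 ± 3.55. None of these passed (adjusted p from 0.404 to 0.978). Cd274 was at 32.1 ± 23.3 against 34.9 ± 14.3 and H2-K1 at 1200 ± 646 against 1210 ± 212. Of ligands, Raet1e was at 30.9 ± 6.8 against 30.9 ± 1.73, and Pvr, which binds TIGIT and DNAM-1, at 32.3 ± 3.23 against 40.4 ± 3.67 (-0.29 ± 0.12, adjusted p = 0.294).

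Autosomal genes called numbered 0 by edgeR, which had 3087 genes at an unadjusted p under 0.05, while DESeq2 called 544 genes (236 higher, 308 lower), voom 6 and the unfiltered fit 14. The count of 3 was 0 without male 5, male 6 or male 8 (adjusted p of the 3 genes 0.0526 to 0.0969). Of the 3, Uty and Eif2s3y also had an adjusted p above 0.05 without male 7 (0.0721 and 0.06) and Eif2s3y without female 4 (0.0641). Of 23 glycolysis and hypoxia genes 0 were called, or 14 lower in female hosts when adjusted over the list alone (camera 5.6e-08, but adjusted p = 0.963 with an estimated correlation). Of 22 oxidative phosphorylation genes 0, or 8 higher when adjusted over the list alone (camera 3.77e-06, but adjusted p = 0.963 with an estimated correlation). Of the 12 skeletal muscle genes 0 were called, also when adjusted over the list alone (camera 0.00508, but adjusted p = 0.963 with an estimated correlation). Muscle content differed between tumours, and 5 muscle genes summed to 1230, 16900, 2230 and 27200 CPM in females 1 to 4 and to 3470, 598, 7910 and 2260 in males 5 to 8. None of 41 lists held with an estimated correlation, against 6 with the preset correlation, 3 higher and 3 lower. Without females 2 and 4 and male 7, the tumours richest in muscle transcripts, edgeR called 0 genes, with 3106 at an unadjusted p under 0.05.

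**Figure D5:**
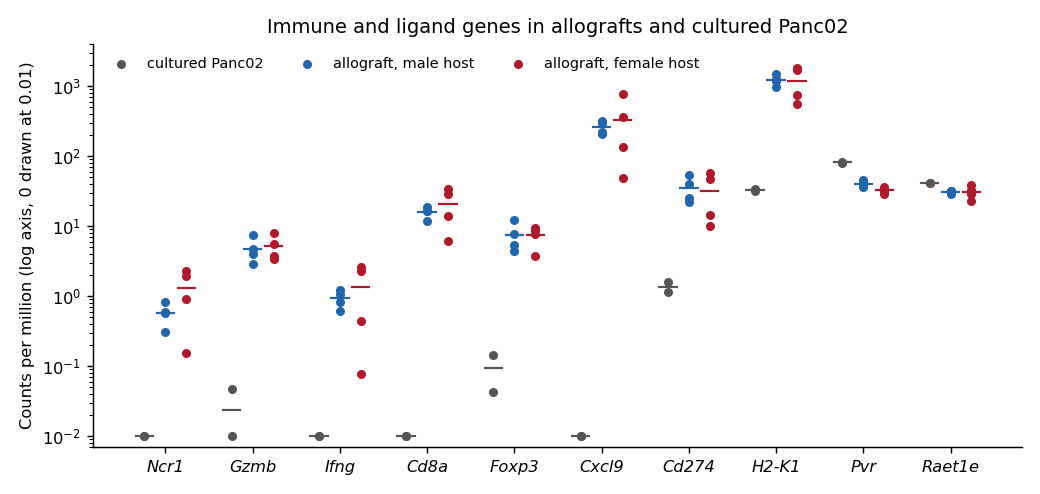
Levels in CPM of immune and tumour genes in each allograft (points) of female and male hosts, with the group mean as a line, on a logarithmic axis where 0 is drawn at 0.01. Cxcl9 averages 329 in female and 261 in male hosts and Raet1e 30.9 in both.

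Allografts held transcripts of many cell types that cultured Panc02 cells lacked, and had lower levels of cell cycle and biosynthesis genes. Lyz2, the lysozyme of macrophages, had 0 counts in culture and stood at 2480 ± 767 CPM in female and 1920 ± 521 in male hosts (SD, n = 4 each), at least 64500-fold higher. The collagen gene Col1a2 was at least 170000-fold and the class II presentation gene H2-Aa at least 43700-fold higher. Cxcl9, a chemokine induced by interferon gamma, was at least 8860-fold, Cd8a at least 539-fold, Ifng at least 34.3-fold and Ncr1 at least 28.4-fold higher. Of 17 macrophage genes 16 rose and 1 fell, and all 15 fibroblast, 12 endothelial and 12 T cell genes rose, with equal counts when adjusted over the list alone (camera 1.74e-31, 2.74e-16, 8.54e-11 and 6.78e-08, but adjusted p = 0.0658, 0.0732, 0.15 and 0.167 with an estimated correlation). All 23 interferon gamma response genes rose, also when adjusted over the list alone (camera 7.57e-15, but adjusted p = 0.174 with an estimated correlation). H2-K1 rose by 5.27 ± 0.58 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 3.64e-05) and Cd274 by 4.68 ± 0.89 (adjusted p = 0.00167).

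All 31 cell cycle, all 18 ribosome biogenesis and all 18 cholesterol synthesis genes fell in allografts, also when adjusted over the list alone (camera 2.19e-17, 1.39e-17 and 2.96e-12, but adjusted p = 0.167, 0.0658 and 0.167 with an estimated correlation). Examples are Top2a (-1.89), Lss (-2.10) and the serine synthesis enzyme Psat1 (-2.48). Rasef, at 28.7 CPM in culture, fell by 9.29 ± 0.61, and the cadherin gene Cdh6 by 5.81. Of 8 epithelial genes 6 fell, also when adjusted over the list alone (camera 0.0145, but adjusted p = 0.354 with an estimated correlation), among them Krt19 (-2.60). Pvr fell by 1.10 (adjusted p = 6.94e-06), Tigit, which Panc02 cells express in culture, by 4.03, and Raet1e did not pass (-0.36, adjusted p = 0.0635). In all, 9015 genes rose and 5432 fell, and camera called 32 of 42 lists, of which 0 held with an estimated correlation. Host cells dilute tumour transcripts in these libraries, so a fall here is relative to all RNA of the tumour.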

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

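The tests of the interferon gamma response genes were chosen after the results had been seen.

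Co-culture differed from monoculture at most genes tested, with 7784 called higher and 8260 lower. Of the 7784, 6589 (84.6%) needed no more than the estimated Panc02 share of 93.4%, which is consistent with RNA carried over from Panc02 cells as the source of most of these calls. Of the 8260, 8236 (99.7%) were higher in monoculture than in cultured Panc02, and across 21414 genes, which are not independent replicates, log2(CPM + 1) in co-culture correlated with cultured Panc02 at r = 0.987 and with monoculture at 0.799. Of the 35 splits of the 8 libraries, the real one called 14679 genes in a fit of both groups and the highest of the others called 0 by edgeR. That argues against chance but does not exclude it, since 1 in 35 is the smallest share such splits can give. Other splits mix the conditions within groups, which widens their spread and keeps their calls low. What stays open is how far either cell type responded to the other beneath this mixture.

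Interferon gamma response genes were higher in co-culture with female than with male NK cells, with a median log2 difference of 1.04 (SE of the median 0.0954, 23 genes). The SEs of medians here are over the genes of the list, which are not independent replicates. They do not measure the spread between libraries. More NK RNA at the levels of fresh or monocultured NK cells is argued against for the 8 members in which it makes up under 10% of the value, since their median was 1.17 (SE 0.123). Between libraries the evidence is weaker. Of the 8, 3 were called over all genes and 8 when adjusted over the list alone. The camera adjusted p was 0.254 with an estimated correlation of 0.781. A difference already present in monoculture is also argued against over the 23 genes, as the median there was -0.0432 (SE 0.0852), or -4.17% of that in co-culture. For the 8 members with little NK RNA that test says little, since a difference in monoculture could hardly carry into their co-culture values. For the other 15 members (median 0.972, SE 0.121), and for the 8 if NK cells make more of them in co-culture, more NK RNA cannot be told apart from other explanations, because the log2 ratio of NK shares was 0.702 between means, 0.975 between the largest and smallest library and 1.2 by Xist over Ddx3y, from which the median of the 8 lay -0.0288 away. Open as hypotheses are more interferon gamma per NK cell, which may act on Panc02 cells and which Ifng relative to the NK-restricted genes does not settle (0.54 ± 0.28, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.763), and, untested, a larger number of NK cells and the sex of the NK donors.

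Between female and male fresh NK cells 2067 autosomal genes were called. Transcripts found only in cells that are lost in culture are argued against as the source of most of them. Of the 2067, 126 (6.1%) had a fresh level over 4 times that in monoculture, against 2045 of 20692 autosomal genes tested (9.88%). The test cannot see genes that such cells share with NK cells, nor other cells that last through culture, so these sources stay open. Of those 126 genes, 28 were higher and 98 lower in female cells. The total of 2149 calls, sex-linked genes included, became 569 without fresh female 1, 1031 without fresh male 4, 916 without fresh male 5 and 3421 without monoculture female 2. A difference in how the cells were sorted, differences between single animals and sex itself may each stand behind these calls and stay open as untested.

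The interaction of sex with condition, a test of the difference between female and male effects, drew attention to further results. The effect of co-culture differed at 217 genes, or at 126 without co-culture female 2 and 92 without co-culture male 5. Gzmb had a log2 fold change 1.07 higher with female cells, Prf1 1.10, Ifng 1.23, Klrk1 0.84 and Ncr1 0.75. Without co-culture male 5 the first 4 of these lost their calls (adjusted p = 0.0985, 0.116, 0.201 and 0.0955, edgeR with Benjamini-Hochberg adjustment), and each lost it in 2 to 6 of the 12 fits without a library. The estimated NK share was 1.63 times as high with female cells, and with scaling over the NK-restricted genes the differences were 0.37, 0.37, 0.54, 0.12 and 0.05. There edgeR called 0 of 319 genes, with 21 at an unadjusted p under 0.05, and DESeq2 and voom 0 each. On simulated counts edgeR recovered 40% of 2-fold changes in that test, so differences of this size could be missed. The effect of culture differed at 546 genes, a count that lay between 180 without fresh male 5 and 935 without fresh female 2. Among them, the log2 difference was 2.15 for Il1rl1, 1.43 for Tigit, -1.41 for Cx3cr1 and -1.23 for Apoe, where Tigit lost its call without fresh female 1 (adjusted p = 0.0794) and Cx3cr1 without monoculture female 2 (0.0779).

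Single allografts stood apart from the other 3 of their group by Dixon's test in 4 of 72 groups of 4 values, where about 1 in 20 groups would by chance. Among male hosts, Xist was at 8.94 CPM in male 7 against 0.523 to 1.1 in the others. Cdh6 was at 5.42 CPM in male 6 against 0.059 to 0.256, and Raet1e at 28.3 CPM in male 5 against 31.4 to 32.1. Among female hosts, Lyz2 was at 3620 CPM in female 1 against 1950 to 2210. In 3 further groups a single female had any counts, which fixes the outcome of the test, so these say nothing: Ddx3y at 0.55 CPM in female 1 (19 counts), Kdm5d at 0.0765 in female 3 (2 counts) and Rasef at 0.0758 in female 4 (3 counts).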

How the results depend on the processing

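The comparisons with cultured Panc02, of genes with little NK RNA and of NK-restricted genes, and the settings that leave out muscle-rich tumours, genes with over 10% NK RNA or TMM, were chosen after the data had been seen.

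Of 104 alternatives over 18 comparisons, other than leaving out a library, 79 gave a count within 1.5 times the main one, as did 136 of 170 fits without a library. For genes named in the text, 1304 of 1356 values under other settings and 2172 of 2278 without a library kept their side of the threshold and, if called, their direction, and 0 called genes reversed. Of the 185 called genes named, 29 lost their call without some single library. Of the shifts that other scalings gave to the median log2 fold change of all genes, the largest in size was -0.238, for the NK-restricted genes with their total alone, where 59 rose and 122 fell against 77 and 70, and -0.0637 in comparisons over all genes.

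Counts that moved by over 1.5 times are given here, and the cause was not tested unless stated. Without the filter on low counts, which adds genes, the co-culture interaction with sex had 529 calls, sex in monoculture 207, sex in co-culture 444, host sex 14, genes with little NK RNA 157 and the summed counts 2082. DESeq2 gave 337 for the co-culture interaction, 1452 for the culture interaction (901 higher and 551 lower, against 215 and 331), 75 for sex in monoculture, 544 for host sex (236 and 308, against 0 and 3), 53 for genes with little NK RNA and 1332 for the summed counts (779 and 553, against 9 and 24). Voom gave 83 for the co-culture interaction, 122 for sex in co-culture, 6 for host sex and 6 for the summed counts. With the libraries of the compared groups alone, which leaves fewer degrees of freedom, the culture interaction had 323 calls, sex in fresh cells 1340, in monoculture 12 and in co-culture 176. Over genes with under 10% NK RNA, fewer genes by construction, sex in co-culture had 16. Without the 3 muscle-rich tumours, fewer samples, host sex had 0 by edgeR, with 3106 genes at an unadjusted p under 0.05. Over 12 libraries, voom with the sample number as a random effect (estimated correlation -0.0255) gave 757 for sex against 33 in sums. Of 183 gene list calls in the 12 comparisons set before the data were examined, 54 held with an estimated correlation, and fry gave 204, and in the 6 comparisons added later the counts were 71, 27 and 67.

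Leaving out single libraries gave 92 to 288 for the co-culture interaction (126 without co-culture female 2, lowest without male 5) and 180 to 935 for the culture interaction. For the latter the count was 186 without fresh female 1, 935 without fresh female 2, 347 and 180 without fresh male 4 and 5, 274 without monoculture male 5, and 355 and 352 without co-culture male 4 and 5. Sex in fresh cells ranged from 569 (without fresh female 1) to 3421 (without monoculture female 2), with 1031 and 916 without fresh male 4 and 5. Sex in monoculture ranged from 17 to 71 (71, 53 and 43 without monoculture female 1, female 2 and male 4), and sex in co-culture from 131 (without male 5) to 303, with 176 without female 2. Host sex ranged from 0 by edgeR (without male 5, 6 or 8, with 3006, 1905 and 2510 genes at an unadjusted p under 0.05) to 4. Co-culture against cultured Panc02 had 1527 to 3530 (1527 and 1934 without Panc02 1 and 2), with female NK cells 1347 to 2394 (1347 and 1564) and with male NK cells 1318 to 3161 (1318 and 1829, and 1791 and 1919 without co-culture male 4 and 5). Genes with little NK RNA had 29 to 119 (highest without co-culture female 2), and the summed counts 5 to 3092 (1625, 3092, 9 and 5 without sample 1, 2, 4 and 5). With 1 library left in a group, that library is assumed to vary like those of the other groups.

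Sample numbers were also tried as a replicate block. Deviations of same-numbered libraries correlated across 21414 genes at 0.00189 to 0.0744 over 6 pairs of conditions. All were under 0.1, and the main fits did not treat the libraries as pairs. Pairs with co-culture, which is mostly Panc02 RNA, could hardly show an effect of the NK donor, and each group had 2 libraries. The library names carry the same prefix for all libraries of a number, so a shared source is not excluded. With the block the culture interaction had 338 calls, the co-culture interaction 212, co-culture against monoculture 15598, monoculture against fresh 8614, and the NK-restricted genes 158, with 2 in their interaction with sex, where edgeR without the block had 0 (21 at an unadjusted p under 0.05), as had DESeq2 and voom.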

Other observations

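The counts of splits for the NK-restricted genes and for Y-linked genes were chosen after the results had been seen.

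Monocultured NK cells also differed from fresh cells in signalling, folding and metabolic genes. Of 17 genes of the TGF-beta response and of ILC1, innate lymphocytes related to NK cells, 13 rose and 1 fell, also when adjusted over the list alone (camera 2.53e-15, but adjusted p = 0.0821 with an estimated correlation). Rgs16, a regulator of G protein signalling, rose by 4.67 ± 0.17 on the log2 scale (SE, edgeR with Benjamini-Hochberg adjustment, adjusted p = 1.42e-12), the Smad inhibitors Ski and Skil by 1.94 ± 0.07 and 1.62 ± 0.07, and Tgfbi, a matrix protein, fell by 5.69 ± 0.71. Of 19 immediate early genes 16 rose and 0 fell, also when adjusted over the list alone (camera 1.68e-08, but adjusted p = 0.222 with an estimated correlation). The transcription factor Egr2 went from 6.35 ± 0.466 and 8.64 ± 1.09 CPM in female and male fresh cells to 71.1 ± 15.4 and 85.1 ± 7.48 (SD, n = 2 each). Of 16 cytokine and chemokine genes 12 rose and 2 fell, or 12 and 3 when adjusted over the list alone (camera 8.18e-06, but adjusted p = 0.105 with an estimated correlation). The chemokines Ccl4 and Xcl1 rose by 1.83 ± 0.11 and 1.44 ± 0.09 and the cytokine Osm by 1.87 ± 0.11, while Ccl5 and Csf1 fell by 1.49 ± 0.14 and 1.97 ± 0.30. Of 11 heat shock genes 10 fell and 0 rose, also when adjusted over the list alone (camera 1.68e-08, but adjusted p = 0.121 with an estimated correlation). The chaperone Hspa8 went from 3110 ± 282 and 2840 ± 409 to 1170 ± 186 and 1160 ± 1.09 CPM. Of 18 ribosome biogenesis genes 17 fell, or 18 when adjusted over the list alone (camera 1.29e-05, but adjusted p = 0.323 with an estimated correlation), such as Npm1 (-0.71 ± 0.06). Of 18 cholesterol synthesis genes 11 rose and 3 fell, or 12 and 3 when adjusted over the list alone (camera 0.00151, but adjusted p = 0.269 with an estimated correlation). Of 23 glycolysis and hypoxia genes 10 rose and 8 fell, also when adjusted over the list alone (camera 0.0209, but adjusted p = 0.486 with an estimated correlation), with Vegfa at 2.38 ± 0.10, Aldoa at 1.46 ± 0.05 and Ldha at -0.53 ± 0.05.

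Beside the lists already described, allografts differed from cultured Panc02 in chemokines, matrix genes and ligands of NK cells. Of 20 chemokines 18 rose and 0 fell (camera 3.64e-08, but adjusted p = 0.163 with an estimated correlation). Ccl7, which attracts monocytes, had 0 counts in culture and stood at 43.5 ± 19.8 and 36.1 ± 8.55 CPM in female and male hosts (SD, n = 4 each), at least 1180-fold higher. All 8 regulatory T cell, all 12 dendritic cell and all 12 skeletal muscle genes rose (camera 0.000523, 2.19e-06 and 0.0146, but adjusted p = 0.261, 0.0658 and 0.525 with an estimated correlation). Foxp3 rose by 6.37 ± 0.73 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 2.75e-05) and Ccr7, a receptor of migrating dendritic cells, by 6.18 ± 0.51. Of 15 matrix remodelling genes 13 rose and 1 fell (camera 6.69e-07, but adjusted p = 0.0769 with an estimated correlation). The metalloproteinase inhibitor Timp3 rose by 6.80 ± 0.45 and the collagen crosslinker Loxl2 by 7.91 ± 0.50. Spp1, abundant in culture at 4290 CPM, fell to 1780 ± 654 and 2220 ± 608 (-1.05 ± 0.29, adjusted p = 0.00969, and 0.0634 or 0.0581 without cultured Panc02 1 or 2). For all these lists the counts were equal when adjusted over the list alone. Of 17 ligands of NK cell receptors 12 rose and 2 fell, or 12 and 4 when adjusted over the list alone (camera 0.00645, but adjusted p = 0.215 with an estimated correlation). Clec2d, a ligand of inhibitory receptors, rose by 8.43 ± 0.68 and the adhesion ligand Icam1 by 3.12 ± 0.26, and the death receptor gene Tnfrsf10b fell by 1.82 ± 0.17. Of 14 NK identity genes 12 rose and 1 fell, also when adjusted over the list alone (camera 0.0142, but adjusted p = 0.523 with an estimated correlation). Nkg7 was at least 435-fold higher, and the gene that fell was Eomes, at 18.7 CPM in cultured Panc02 itself (-2.88 ± 0.26).

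Single tumours stood apart in transcripts of other cell types, in genes chosen after their values were seen. The B cell gene Ms4a1 stood at 25.5 CPM in female 3 and at most at 0.826 in the other 7 tumours. The keratin genes Krt14 and Krt5 stood at 106 and 50.1 CPM in male 7 and at most at 11.2 and 6.52 elsewhere. Male 7 was also the tumour with Xist at 8.94 CPM, and muscle genes summed to 27200 CPM in female 4 and 16900 in female 2 against 598 in male 6.

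Other splits of the same libraries were counted for 3 further comparisons, each over 35 splits of 8 libraries into 4 and 4 and in a fit of both groups alone. For monoculture against fresh cells the real split called 7278 genes and the highest other 6, so that 1 split, the real one, gave as many. For NK-restricted genes in co-culture against monoculture the counts were 144 genes against 0 by edgeR. Both argue against chance but do not exclude it, since 1 in 35 is the smallest share such splits can give. Other splits mix the conditions within groups, which widens their spread and keeps their calls low. For host sex of allografts the number of genes does not exclude chance, as 2 splits gave at least the 3 genes of the real one. All 3 genes called are Y-linked, of 16 such genes tested, and the highest other split called 0 of them by edgeR. That count cannot decide about chance, since Y-linked genes follow the sex of the host and every other split mixes the sexes. The split of females 1, 2 and 4 with male 5 against female 3 with males 6, 7 and 8 called 49 genes, many times the real count. That split was picked as the highest after counting, and whether it reflects a structure of the tumours other than host sex was not tested.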
